A study of Arabidopsis thaliana with 6 samples.

How the data were processed

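Seedlings of Col-0 and of the atsf1-2 mutant were harvested 9 days after plating, per the labels' protocols, and 300 ng of total RNA per sample were labelled with biotin and hybridised to ATH1 arrays. The deposited values are 1 signal intensity per probe set and array on a linear scale. The authors made these intensities with MAS5 in Affymetrix Expression Console 1.2, per the submitters' processing notes. The trimmed mean of each array, without the lowest and highest 2% of signals, was nearly equal on all arrays, as computed from the deposited values. Settings for background and detection are not given in the sources used here. Samples were grouped by genotype from their titles, which call the 3 samples of each genotype biological replicates.

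Of 22810 probe sets, 64 were controls and were left out of the tests. Among the other 22746 probe sets, the platform annotation named 1 gene for 13513, several for 503 and none for 8730. Gene names were updated through gene identifiers to the RefSeq table of assembly TAIR10.1, which matched 13436 probe sets. That table was used for names and for the order of neighbouring genes. In an exploratory look, log2 fold changes tended to be lower for genes that are longer in that table, with trends of single arrays that overlapped between genotypes. Since no genome build is given for the arrays, gene length is not used here in any reported test and no value is given. Probe sets with several genes or none are not named. Of protein-coding genes with a symbol of their own in that table, 14.6% had a probe set paired with them alone, against 63.1% of those without one. Rankings of named genes therefore leave out many genes that are known by a symbol.

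Signals were taken to log2 with no further scaling, and probe sets were kept when their mean log2 signal over the 6 arrays was at or above the 40th percentile, which left 13648. Genotypes were compared with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with a trend on the mean signal), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Standard errors are those of limma's moderated fit. The fit was tested on simulated data for 3 arrays against 3, with 50 changed probe sets of each size. It called 6% with a simulated log2 change of 0.5, 68% with 1 and 100% with 2, and it called 8 of 13448 unchanged ones. The simulated noise was drawn independently for each value and alike for all arrays. The count of unchanged probe sets called therefore does not carry over to the real arrays.

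Before the data were examined, 20 gene lists with 418 loci were fixed, of which 63 loci had a named probe set. Lists with at least 3 tested members, a minimum chosen later, were compared with all other probe sets by limma's camera with a preset correlation of 0.01, adjusted over 10 lists. Of the lists that passed, heat shock also passed with an estimated correlation, and flavonoid synthesis did not. The fry test asks whether the members of a list move one way on balance. Lists of ribosomal proteins and of intronless genes were not used here.

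The rule for named genes was also fixed before the data were examined. It takes AtSF1, then the 10 largest rises and the 10 largest falls among probe sets past the threshold that name 1 gene and whose genotypes do not overlap. From each list it takes up to 4 members past the threshold, or up to 2 with the smallest p where none passed. The tested members AT5G51440, UGT78D2, COR47 and PYK10 were named in addition, to complete the lists they belong to, after their values were seen. The named low-oxygen and mitochondrial stress genes outside the rule and the neighbouring loci were also chosen after their values were seen. Ratios of 3' to 5' control probe sets and root markers were compared with exact permutation tests, whose smallest p is 0.1.

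The alternatives were no filter, a filter at the 60th percentile, a pseudocount of 38.4 (the 25th percentile of all signals), quantile normalization, centring on each array's median, eBayes without a trend, array weights, the replicate number as a block, the mean of all probe sets of a gene for the lists, and leaving out each array in turn. Later additions left out, or modelled with a term, the 2 arrays that stood apart.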

Results

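Transcript levels were measured in whole seedlings of Arabidopsis thaliana on ATH1 arrays, which carry sets of short probes for most genes of the plant. Col-0, the reference accession, was compared with atsf1-2, a mutant of AtSF1, a protein that takes part in pre-mRNA splicing. Each genotype had 3 biological replicates, 1 array each, from seedlings grown on agar for 9 days at 23 C under 16 h of light and 8 h of dark. The median signal of an array lay between 165 and 196, and the signals had been scaled to one trimmed mean. Arrays of Col-0 correlated with each other at Pearson's r of 0.975 to 0.990 across probe sets, arrays of atsf1-2 at 0.965 to 0.984, and arrays of different genotype at 0.945 to 0.970. The number of arrays limits the precision of every value.

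The comparison asked which transcripts differ in seedlings when AtSF1 is mutated. Genes for small heat shock proteins, chaperones that bind unfolding proteins, were far higher in atsf1-2. The signal of ATHSP22.0 (AT4G10250) rose from 107 ± 78.5 (SD, n = 3) in Col-0 to 1652 ± 272 (SD, n = 3) in atsf1-2, a log2 fold change of 4.16 ± 0.37 (SE, limma adjusted p = 0.000168). Its Col-0 signal was 198 on replicate 2 and 64.1 and 59.9 on the other arrays, and without that replicate the log2 fold change was 4.72. AT1G53540 rose from 513 ± 69.8 to 3524 ± 264, and AT2G29500 rose from 1688 ± 433 to 6495 ± 559 (SD, n = 3 for each). All 5 heat shock genes that could be tested, of 28 in the list, rose, and all 5 also passed when adjusted over the list alone. The other members were AT1G52560, with a log2 fold change of 3.03 ± 0.24 (SE), and AT5G51440, with 1.32 ± 0.13 (SE). The mean log2 fold change of the list was 2.65 (camera adjusted p = 2.92e-13, and adjusted p = 0.0418 with an estimated correlation). All 5 tested members encode small heat shock proteins, so the list result describes that family. No heat shock factor or large chaperone of the list could be tested.

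**Figure D1:**
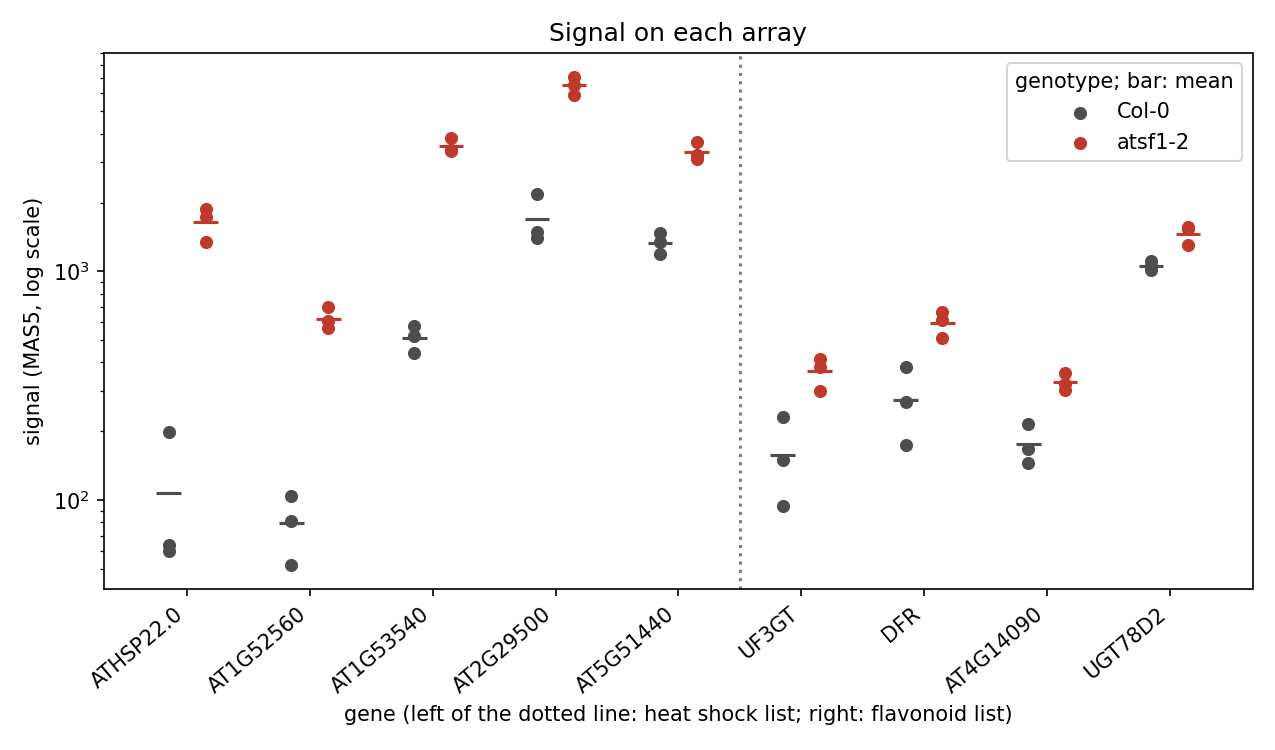
Signal of each array on a log scale for the tested members of the heat shock list (left of the dotted line) and of the flavonoid list (right), with 3 points and a bar at the mean for each genotype. For ATHSP22.0 the mean signal was 107 in Col-0, where 1 array lay at 198 and the others at 64.1 and 59.9, and 1652 in atsf1-2, and the points of the genotypes do not overlap for any gene shown.

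Of 20 listed genes of flavonoid and anthocyanin synthesis, the pathway of red and purple pigments, 4 could be tested and 3 rose in the mutant, but the list as a whole did not pass with an estimated correlation (adjusted p = 0.282). DFR (AT5G42800), the dihydroflavonol reductase, rose from 275 ± 103 to 596 ± 78.2, and UF3GT (AT5G54060), a glycosyltransferase acting on anthocyanins, rose from 158 ± 68.5 to 365 ± 59.0 (SD, n = 3 for each). AT4G14090, another glycosyltransferase of the pathway, rose with a log2 fold change of 0.91 ± 0.19 (SE, limma adjusted p = 0.0177). UGT78D2 had a log2 fold change of 0.46 ± 0.13 (SE) and did not pass (limma adjusted p = 0.0507), but it passed with the 60th percentile filter, a pseudocount, quantile normalization, median centring, array weights or a term for the arrays that stand apart (limma adjusted p from 0.022 to 0.04995). All 4 passed when adjusted over the list alone. The mean log2 fold change of the list was 0.96 (camera adjusted p = 8.9e-05 with the preset correlation). Leaving out Col-0 replicate 2 or Col-0 replicate 3 ended the calls of DFR (limma adjusted p = 0.0634 and 0.0514), UF3GT (0.0709 and 0.0628) and AT4G14090 (0.0585 and 0.0749). Leaving out atsf1-2 replicate 1 ended those of UF3GT (0.0879) and AT4G14090 (0.0514), and leaving out atsf1-2 replicate 2 ended that of UF3GT (0.0531). Leaving out Col-0 replicate 2 and atsf1-2 replicate 3 together ended those of DFR (0.0692) and AT4G14090 (0.0509). In the fits that ended these calls the log2 fold changes were 0.89 to 1.2 for DFR, 0.96 to 1.3 for UF3GT and 0.78 to 0.97 for AT4G14090.

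Among probe sets that the annotation pairs with 1 gene, the 10 largest rises included 5 genes for small heat shock proteins. These were 4 from the list, and AT5G37670, which rose from 617 ± 60.4 to 4610 ± 306 (SD, n = 3 for each). Probe sets with no gene listed are outside this ranking, and 2 of them rose with log2 fold changes of 3.28 and 3.21. AT1G43590 rose from 63.3 ± 4.85 to 857 ± 69.4, a log2 fold change of 3.76 ± 0.16 (SE, limma adjusted p = 5.4e-07). AT2G21640, known as a marker of oxidative stress, rose from 189 ± 22.2 to 1414 ± 236, and AT2G04050, which encodes a transporter of the MATE family, rose from 57.5 ± 20.3 to 389 ± 43.0 (SD, n = 3 for each). AT2G41730 and AT3G10020 rose with log2 fold changes of 1.84 ± 0.22 and 1.77 ± 0.14 (SE). The lowest signal kept by the filter, as a geometric mean over the 6 arrays, was 104.44. In Col-0 the mean signals of AT1G43590, AT1G52560 (79.2) and AT2G04050 lay below that value. With the pseudocount the log2 fold changes of these genes and of ATHSP22.0 were smaller but still passed. The sizes of these rises therefore depend on how dim signals are treated.

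Among probe sets paired with 1 gene, the largest fall was that of AT1G06690, a member of the aldo/keto reductase family. Its signal fell from 697 ± 36.2 in Col-0 to 110 ± 12.6 in atsf1-2 (SD, n = 3 for each). Its log2 fold change was -2.66 ± 0.16 (SE, limma adjusted p = 4.77e-06). AT2G29300, which encodes a protein related to tropinone reductases, fell from 351 ± 127 to 78.3 ± 35.6. LSMT-L (AT1G14030), related to a methyltransferase of Rubisco, fell from 284 ± 58.9 to 76.2 ± 15.4, and QQS (AT3G30720), a gene known for its effect on leaf starch, fell from 765 ± 173 to 205 ± 42.5 (SD, n = 3 for each). The log2 fold changes of AT4G03200, AT5G59130, AT1G57770, AT2G19930 and AT4G30993 lay between -1.69 and -1.51. In atsf1-2 the mean signals of AT2G29300, LSMT-L, AT5G59130 (71.2) and AT2G19930 (60.7) lay below 104.44, the lowest geometric mean kept by the filter. With the pseudocount the falls of these genes were smaller but still passed, so their sizes depend on how dim signals are treated. AT3G59780 fell with a log2 fold change of -1.64 ± 0.37 (SE, limma adjusted p = 0.0257). Its call ended without Col-0 replicate 1 (limma adjusted p = 0.0909), without Col-0 replicate 3 (0.0778) or without atsf1-2 replicate 2 (0.0571).

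**Figure D2:**
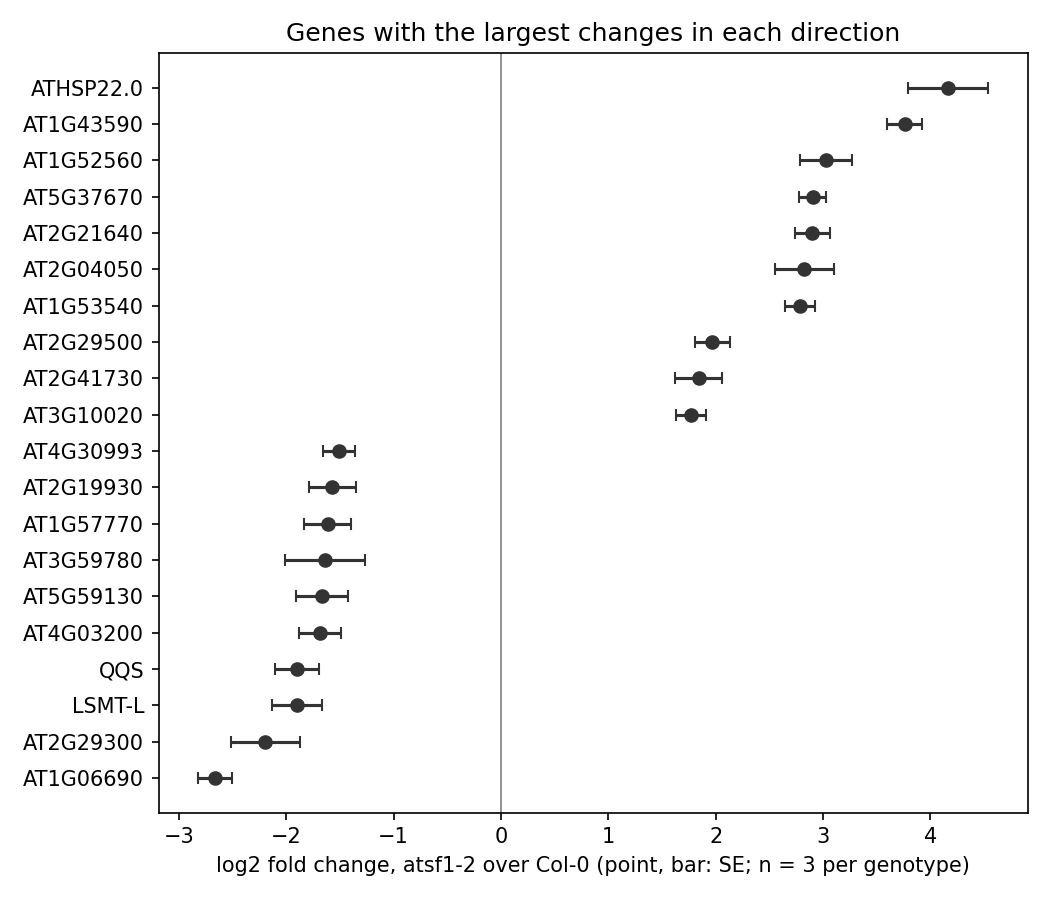
Log2 fold change of atsf1-2 over Col-0 (point) with its standard error (bar), 3 arrays per genotype, for the 10 genes with the largest rise and the 10 with the largest fall among genes past the threshold. The values run from 4.16 for ATHSP22.0 to -2.66 for AT1G06690.

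The few genes of the splicing list that could be tested gave no call. None of the 6 tested members, of 43 in the list, passed limma's adjusted threshold, and U2AF35B had the smallest p, with a log2 fold change of 0.25 ± 0.13 (SE, limma adjusted p = 0.25; unadjusted p = 0.0793). PRP39 had a log2 fold change of 0.18 ± 0.17 (SE). On the log2 scale the mean of the list was 0.057, above 0, and its median -0.0017, below 0, and camera placed it upward (adjusted p = 0.688, and adjusted p = 0.982 with an estimated correlation). Of 4 tested factors of nonsense-mediated decay, which removes transcripts with early stop codons, none passed over all probe sets and 1 passed when adjusted over the list alone. That gene was AT2G39260, with a log2 fold change of -0.69 ± 0.20 (SE, limma adjusted p = 0.0596). It passed over all probe sets by eBayes without trend (limma adjusted p = 0.0475), with array weights (0.0261), without atsf1-2 replicate 2 (0.0458) and with a term for the arrays that stand apart (0.0301). AT1G15280 of the same list had a log2 fold change of 0.30 ± 0.16 (SE). AT5G51300, the AtSF1 gene itself, is not analysed here, because the annotation used here pairs no probe set with it alone, so the genotype labels were not checked against it.

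Among flowering time genes, LD (AT4G02560), a regulator of flowering, fell from 238 ± 11.4 to 121 ± 29.8 (SD, n = 3 for each; limma adjusted p = 0.0182), and the other 3 tested members did not pass. Among cold response genes, LTI30 (AT3G50970), a dehydrin, rose from 779 ± 82.5 to 1329 ± 107 (SD, n = 3 for each; limma adjusted p = 0.00978), while COR47 had a log2 fold change of 0.58 ± 0.17 (SE, limma adjusted p = 0.0554). COR47 passed with median centring (limma adjusted p = 0.0325), with array weights (0.0424), without atsf1-2 replicate 1 (0.0235) and with a term for the arrays that stand apart (0.0211). Of 5 photosynthesis genes encoded in the nucleus, LHCB4.3, an antenna protein, rose with a log2 fold change of 0.56 ± 0.15 (SE, limma adjusted p = 0.0487). HAT2, a homeobox gene induced by auxin, fell, with a log2 fold change of -0.58 ± 0.15 (SE, limma adjusted p = 0.0416), and 3 other tested auxin genes did not pass. Adjusted over the list alone, 1 flowering time, 2 cold response, 2 photosynthesis and 1 auxin gene passed. Leaving out single arrays ended the call of LD without any of the Col-0 arrays or atsf1-2 replicate 1 (limma adjusted p from 0.0622 to 0.0729), and that of LTI30 without Col-0 replicate 3 (0.0514). The calls of HAT2 (limma adjusted p up to 0.186 without Col-0 replicate 1) and LHCB4.3 (up to 0.142 without atsf1-2 replicate 1) ended without most or all of the single arrays, after quantile normalization, with no filter (0.0548 and 0.0673) and by eBayes without trend (0.0562 and 0.0816), and that of HAT2 also with median centring (0.0752).

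In the remaining lists no tested member passed over all probe sets. The log2 fold changes of the members with the smallest p were 0.43 ± 0.27 (SE) for LEA4-5 among genes of the abscisic acid response, -0.34 ± 0.15 (SE) for TIC and 0.24 ± 0.17 (SE) for GI among clock genes, and -0.36 ± 0.13 (SE) for EXPA8 and -0.11 ± 0.12 (SE) for EXPA4 among cell wall genes. They were 0.16 ± 0.15 (SE) for GID1A and -0.14 ± 0.24 (SE) for GID1C among gibberellin genes, 0.079 ± 0.22 (SE) for PRL and 0.037 ± 0.13 (SE) for SIM among cell cycle genes, 0.11 ± 0.20 (SE) for WRKY6 among senescence genes, and -0.00037 ± 0.24 (SE) for FMA among genes of stomata and trichomes. Adjusted over the list alone, 1 gene, EXPA8, passed, and over all probe sets it passed with array weights (limma adjusted p = 0.0374) and with a term for the arrays that stand apart (0.0397). Of 10 lists tested as a whole, the 8 other than heat shock and flavonoid synthesis did not pass (camera adjusted p from 0.0774 to 0.976). No member of the lists for salicylic acid and immune response, jasmonate and ethylene defence, seed storage or floral organ identity could be tested.

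**Figure D3:**
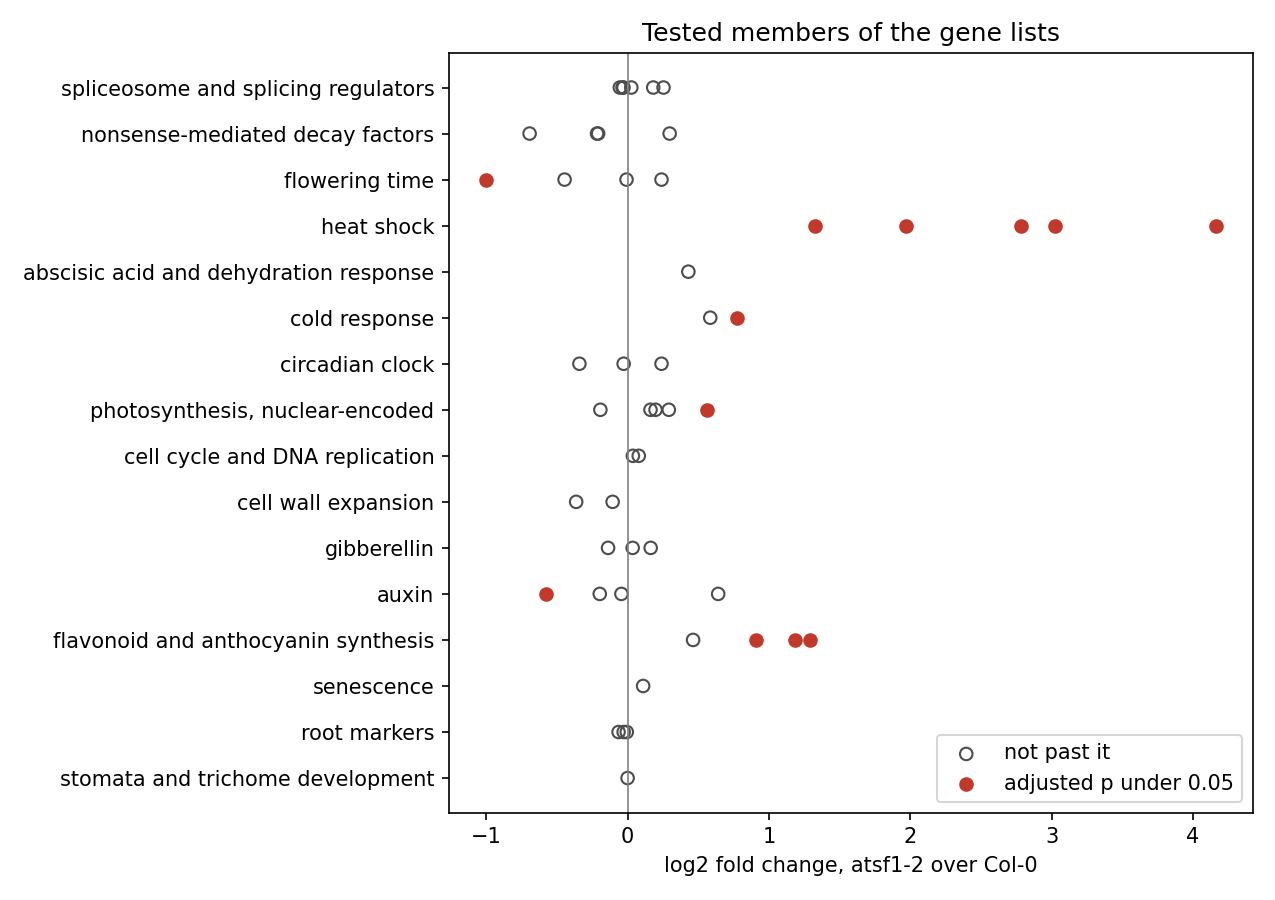
Log2 fold change of atsf1-2 over Col-0 for each tested member of the gene lists, 1 circle per gene, filled where the adjusted p was under 0.05. All 5 heat shock genes lie to the right, between 1.32 and 4.16, while the 6 splicing genes lie between -0.055 and 0.25.

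Root markers differed between genotypes by less than the spread between arrays. The median log2 signal of EXPA7, EXPA18 and PYK10 was 8.84 ± 0.22 (SD, n = 3) in Col-0 and 8.78 ± 0.059 (SD, n = 3) in atsf1-2 (exact permutation p = 0.7, two-sided, where 3 against 3 cannot go below 0.1). On every array this median was the value of EXPA18, which lay between those of EXPA7 and PYK10. The permutation test therefore rests on EXPA18 alone. The separate log2 fold changes of EXPA7, EXPA18 and PYK10 were -0.028 ± 0.18, -0.064 ± 0.15 and -0.0061 ± 0.098 (SE). All 3 turned positive with median centring, those of EXPA7 and EXPA18 also after quantile normalization. The ratio of signals from the 3' to the 5' end of control transcripts, a measure of intact RNA, was on the log2 scale 1.55 ± 0.40 in Col-0 and 1.65 ± 0.30 in atsf1-2 for actin (SD, n = 3; exact permutation p = 0.6). For GAPDH it was 0.0018 ± 0.14 and 0.14 ± 0.059, and for ubiquitin 0.36 ± 0.061 and 0.46 ± 0.080 (SD, n = 3; exact permutation p = 0.2 for each). Each ratio was thus higher in atsf1-2. The difference exceeded the pooled SD within genotypes for GAPDH (0.135 against 0.108) and ubiquitin (0.098 against 0.071), but not for actin (0.094 against 0.35). For the mean of the log2 ratios it was 0.11 against 0.16 (exact permutation p = 0.5). Col-0 replicate 2 and atsf1-2 replicate 3 stood apart from the other arrays, with actin ratios of 2.14 and 2.47 against 3.36 to 3.63.

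Over all 13648 probe sets tested, 409 were higher and 709 lower in atsf1-2 (limma, adjusted p under 0.05), of which 88 and 149 changed at least 2-fold. Those that name 1 gene numbered 208 among the higher and 361 among the lower. Of 519 past the threshold with no gene listed, the 2 that rose most had log2 fold changes of 3.28 ± 0.16 and 3.21 ± 0.16 (SE), and the 2 that fell most had -2.08 ± 0.30 and -1.93 ± 0.38 (SE). The groups did not overlap for 31.3% of tested probe sets, where chance gives 10%. The lower probe sets were 63.4% of those past the threshold, but 51.4% after quantile normalization (469 higher and 497 lower) and 37.0% with each array centred on its median (729 higher and 428 lower), so that the direction in which more probe sets changed depended on the scaling. Median centring moved the median log2 fold change of all probe sets by 0.12, from -0.070 to 0.047. In an exploratory look that is not among the tests reported here, longer genes tended to have lower fold changes, so a bias with length is not excluded for the lower probe sets. Leaving out 1 array gave 140 higher and 151 lower without Col-0 replicate 1, and 154 and 261 without Col-0 replicate 2. It gave 142 and 204 without Col-0 replicate 3, and 130 and 221 without atsf1-2 replicate 1. The counts stayed nearer those of all arrays without atsf1-2 replicate 2 (364 and 693) and without atsf1-2 replicate 3 (463 and 777).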

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

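The fits that left out or modelled Col-0 replicate 2 and atsf1-2 replicate 3 were chosen after the data were seen. Of 27 genes named by the rule and past the threshold, 19 stayed past it under every alternative that gave a value, and none of the 27 changed sign. Of 17 named beyond the rule, 10 passed, 6 of them under every alternative, and 2 that had not passed changed sign. The most calls were lost by LHCB4.3, under 11 of 16 alternatives, and HAT2, under 10 of 16. Of probe sets higher in atsf1-2, 267 passed with no filter, 729 with median centring, 271 by eBayes without trend, 947 with array weights and 892 with a term for the arrays that stand apart. Of the lower ones, 439 passed with no filter, 428 with median centring, 1713 with array weights and 1511 with that term. Leaving out both of those arrays gave 433 and 768. Leaving out each array in turn gave 130 to 463 higher and 151 to 777 lower probe sets. The cause of these moves was not tested. In simulated data the fit called 6% of log2 changes of 0.5 and 68% of changes of 1. Only 50 probe sets of each size were changed there, far fewer than the number called in the real data. Fewer changed probe sets make the adjusted threshold stricter, so these shares do not carry over to the real arrays. The simulated noise was also alike on all arrays, while the weights estimated for the real arrays ran from 0.31 to 2.45. Small changes may still be missed, by a share that was not measured.

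The titles number the replicates but do not say whether samples of the same number were paired. Deviations from the genotype means correlated at 0.10, -0.19 and -0.21 between arrays of the same number. Between arrays of different number they correlated at -0.25 to 0.32. With 3 arrays per genotype, whose deviations sum to 0, these values cannot show whether the samples were paired. With the replicate block, 171 probe sets were higher and 263 lower, and HAT2 (adjusted p = 0.103), LHCB4.3 (0.0701) and AT4G14090 (0.0513) were no longer past the threshold.

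No tested gene of the lists had several probe sets (0 genes), so averaging them could move nothing and is not counted. The heat shock list passed under the other 18 alternatives run, with mean log2 fold changes of 2.42 to 2.85. The flavonoid list lost its call with an estimated correlation (mean 0.96, adjusted p = 0.282) and under none of the 16 others that could move it. The photosynthesis list, not past the threshold, passed by fry (mean 0.20, adjusted p = 0.0302) and without Col-0 replicate 3 (mean 0.24), with means of 0.18 to 0.24 without single arrays. Its mean depended on the scaling, at 0.061 after quantile normalization (adjusted p = 0.853) and 0.32 with median centring (adjusted p = 0.113).

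The remaining changes of direction were in values near 0 that passed under no alternative; their cause was not tested. Camera compares a list with all other probe sets, and placed clock genes and root markers upward although their means were negative. That direction turned for clock genes by fry, with no filter and with the 60th percentile filter (mean -0.043 in each), and for root markers by fry and with no filter (-0.033 in each) and after quantile normalization (-0.0069). It turned for decay factors without both arrays that stand apart (-0.017). Without single arrays, means ran from -0.14 to 0.026 for clock genes, -0.10 to 0.033 for root markers, -0.37 to -0.031 for decay factors and -0.12 to 0.071 for auxin genes. Among named genes, log2 fold changes turned after quantile normalization for EXPA18 (0.049), EXPA7 (0.12) and FMA (0.13), with median centring for EXPA4 (0.011), EXPA18 (0.053), EXPA7 (0.089), PYK10 (0.11) and FMA (0.12), with array weights for EXPA7 (0.046), PYK10 (0.024) and FMA (0.048), and without both arrays that stand apart for EXPA7 (0.13), PYK10 (0.019), AT2G29180 (-0.041) and FMA (0.10). Without single arrays they ran from -0.12 to 0.33 for PRL, -0.010 to 0.097 for SIM, -0.34 to 0.029 for GID1C, -0.18 to 0.038 for EXPA18, -0.13 to 0.11 for EXPA7, -0.058 to 0.039 for PYK10, -0.041 to 0.25 for WRKY6 and -0.18 to 0.20 for FMA.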

Other observations

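Genes that respond to low oxygen, and genes of the mitochondrial stress response, stood among those that rose in atsf1-2. AT3G10020, AT4G10270, AT5G10040 and PDC2 (AT5G54960), which encodes a pyruvate decarboxylase of fermentation, rose with log2 fold changes of 1.77 ± 0.14, 1.03 ± 0.16, 1.04 ± 0.20 and 1.01 ± 0.14 (SE). The call of AT5G10040 ended without atsf1-2 replicate 1 (limma adjusted p = 0.0581). AT2G21640, AT2G04050, AT2G41730, AT5G51440 and AT5G09570 rose with 2.90 ± 0.16, 2.82 ± 0.28, 1.84 ± 0.22, 1.32 ± 0.13 and 1.15 ± 0.17 (SE). AT5G51440 is also in the heat shock list. These genes prompted both lists after their values were seen, so they are no evidence for them. Genes encoded in the plastid did not move as a group: of 61 probe sets, 1 was higher and 1 lower, and the median log2 fold change was 0.012 (camera p = 0.356, and p = 0.72 with an estimated correlation).

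Both lists were therefore tested on members whose values had not been seen, with predictions written before those values were known, whereas the tests on splits of the arrays and on neighbouring genes were chosen after the result was seen. Of 14 unseen low-oxygen genes that could be tested, 4 rose and 1, AT1G72940, fell, with a mean log2 fold change of 0.24. The call of AT1G72940 ended without any of the Col-0 arrays or atsf1-2 replicate 1 (limma adjusted p up to 0.069). Camera gave p = 0.00131 with the preset correlation and p = 0.282 with an estimated correlation. Of 4 unseen mitochondrial stress genes, none passed limma's adjusted threshold and 2 had an unadjusted p under 0.05. Their mean log2 fold change was 0.37, with camera p = 0.0159 and p = 0.0707 with an estimated correlation. A wider response of either kind may exist in the mutant, but these tests leave both hypotheses open.

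For the rise of the heat shock list, technical explanations were weighed against the genotype. Leaving out both arrays that stood apart left the mean log2 fold change at 2.81, and quantile normalization left it at 2.67. The genotypes did not overlap for any tested member of the list. Median centring moved the median log2 fold change of all probe sets by only 0.12. Neither fit could therefore have removed a rise of this size. They show that the rise did not rest on those arrays or on scaling, and they decide nothing about other technical causes. Probes shared between related heat shock genes, or a difference in growth or handling between the genotypes on the day of harvest, may also matter and were not tested. A further test, against the trend with gene length, was thought of after that trend was seen and was not run, so that explanation stays open. The effect of the mutation stays open beside them, as a hypothesis.

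In the order of 7155 named and tested loci, 5 neighbours in a row were lower in atsf1-2: AT2G29210, AT2G29290, AT2G29300, AT2G29310 and AT2G29320, with log2 fold changes of -0.75, -0.93, -2.19, -1.14 and -1.13. A run as long occurred in 0.2% of 10000 shuffled orders, which argues against a chance order of the changed genes. Most of these genes encode related reductases, so that probes shared between them, a local difference between the plant lines, or shared regulation may lie behind the run; none of these was tested. The call of AT2G29210 ended without any of the Col-0 arrays or atsf1-2 replicate 1 (limma adjusted p from 0.0614 to 0.0801) and that of AT2G29320 without Col-0 replicate 3 (0.0538), and the run was not tested in those fits. Before the run, AT2G29180 had a log2 fold change of 0.24, and after it AT2G29330, AT2G29340 and AT2G29360 had -0.23, -0.27 and -0.45, none of which passed, except AT2G29360 without atsf1-2 replicate 3 and with a term for the arrays that stand apart (0.0482 and 0.0433), while the next, AT2G29500, rose by 1.97.

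The real grouping gave 1118 probe sets past the threshold, and the highest count among the other splits of the 6 arrays into 3 and 3 was 0. Each of those splits mixed the genotypes, so that any genotype difference widens the spread within their groups and lowers their counts. The count of 0 therefore does not show what chance alone would give. The real split was the only 1 of 10 with as many, and 10 splits are too few for a share under 0.05.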
